A study of Mus musculus with 8 samples.

How the data were processed

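Chromatin immunoprecipitation with an antibody against HNF6, followed by sequencing (ChIP-seq), was carried out on liver of individual CD-1 mice, an outbred stock. There were 4 female and 4 male libraries. The sample titles carried 1 of 2 tags, G73 or G76, here called library sets; each set held 2 female and 2 male libraries, and the intervals were 35 bp long in set G73 and 40 bp long in set G76. What the tags stand for was not given in the sources used here.

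Each deposited file listed aligned reads, 1 line per read, with chromosome, start, end and strand. The deposited score column held the same value on every line, so it carried no measurement and was not used. Reads were aligned to the mouse build mm9, and the tools named were Bowtie 0.12.7 and MACS2 2.0, per the submitters' processing notes. Which filters preceded deposition was not given in the sources used here. No input library was used here, and neither the genome sequence nor a gene annotation of build mm9 was used. Sites are therefore named by their mm9 position, counted from 1, and the planned comparisons with gene lists, with neighbouring genes and with sequence motifs were left out.

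Reads on the 19 autosomes, X and Y were used. Reads with the same chromosome, strand and 5′ end within a library were counted once, which left 2702885 to 7121922 retained reads per library out of 4120722 to 10864237 deposited ones. Read positions were shifted by 85 bp toward the fragment centre. Strand cross-correlation put the fragment length at 160 to 180 bp.

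Sites were called on a pool to which every library gave 2702885 reads, the size of the smallest library. Reads were counted in 200 bp windows moved in steps of 50 bp and compared with a Poisson expectation. The expectation was the larger of the genome-wide mean over 2.39 Gb of covered sequence and the mean in the surrounding 10 kb. Windows with p below 1e-05 were merged across gaps of up to 100 bp. Sites with a surrounding background above 5 times the genome mean, with more than 3 deposited reads per retained read, or with forward and reverse reads not offset as around a bound position were left out. These 3 filters were set after the data and a first sex comparison had been seen, and an alternative without them was run. They removed 564 of 99332 candidate sites.

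Site calling was tested on simulated data covering 100 Mb with a uniform background: 77.6% of planted sites of 12 reads and 100% of those of 60 reads were found, with 3 calls at other positions. An uneven background was not simulated, so the number of false calls in the real data is not known from this test. Reads were counted in each site in each library, and autosomal sites with at least 10 reads in at least 4 libraries were compared between the sexes. The counts were scaled with a trimmed mean of log ratios, trimming 30% of ratios and 5% of levels at each end. They were fitted with limma-voom (limma 3.58.1, R 4.3.3) with sex and library set as terms. Adjusted p-values are those of limma after Benjamini-Hochberg adjustment over 33330 autosomal sites, and sites with an adjusted p below 0.05 were called. A count model had been planned only for the case that the deposited columns were counts; they were not, and it was not run on the reads counted here.

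On simulated data for the male against female comparison with 33330 sites, 30% of 100 sites changed 2-fold and 86% of 100 sites changed 4-fold were recovered. In that simulation 3 unchanged sites were called, and 0 sites were called when nothing changed. Every simulated site had the same dispersion, 0.0334, the median over the real sites, and no library-set effect. The simulation therefore does not show how many real sites of larger spread are called wrongly. When 6% of sites rose 4-fold in males, the scaling moved the median of the unchanged sites by -0.05 on the log2 scale; when 20% rose, it moved it by -0.21. Levels are given as RPM, here the reads at a site per 1000000 scaled reads in the tested autosomal sites, as mean ± SD over the 4 mice of a sex. Fold differences at autosomal sites are the limma log2 differences put on the fold scale. They can differ from the ratio of the mean levels. Other scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

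X-chromosomal sites with at least 10 reads in at least 2 libraries were tested apart, with the autosomal scaling and adjustment over the X sites alone. Background was read from 185761 bins of 10 kb that held no site. Single values of the 8 libraries were compared with exact permutation tests, two-sided, whose smallest possible p with 4 against 4 mice is 0.0286. These tests exchanged libraries between the library sets as well as within them. Exchange within sets alone leaves 18 splits, where the smallest possible share is 5.56%. Wilson intervals on shares of reads cover counting error only. The sites named were fixed by a rule before the data were examined. It takes the 12 autosomal sites with the smallest adjusted p in each direction among called sites whose 4 female and 4 male values did not overlap, and the 5 sites with the highest mean level.

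The alternatives were other scalings (total retained reads; background bins), all deposited reads, no low-count filter, no library-set term, each library set alone, each library left out, equal depth, limma-trend on log2(RPM + 0.5), sample quality weights, a site threshold of 1e-09, sites called in at least 2 single libraries, reads in 400 bp around the summit, and a 2-fold minimum. For site numbers they also included a genome-wide background, and for overlap a minimum of 50% of the shorter site.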

Results

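HNF6 (ONECUT1), a transcription factor of hepatocytes and bile duct cells, was mapped on chromatin from the livers of 4 female and 4 male CD-1 mice aged 7-8 weeks. The labels set female against male liver, so the comparison made was whether HNF6 bound the same places, and to the same level, in both sexes. After removal of duplicate positions the libraries held 2702885 (female replicate 1), 3193309 (female 2), 7121922 (female 3), 6100753 (female 4), 3770675 (male 1), 2732467 (male 2), 7039084 (male 3) and 3826259 (male 4) reads. Duplicates made up 16.5% (male 4) to 46.9% (male 2) of the reads on assembled chromosomes.

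HNF6 binding was found at 98768 sites in the pooled libraries, 95565 of them on autosomes, 3193 on X and 10 on Y. The sites had a median width of 350 bp and covered 1.61% of the covered genome. In the 200 bp window with the most reads, the median count was 7.87 times the Poisson expectation used for calling. The 10 kb mean behind that expectation includes the reads of the site itself. Sites took up 29.5% ± 2.9 (SD, n = 4) of the reads in females and 30.1% ± 2.4 (SD, n = 4) in males. The number of sites depends on how they are called: it was 62232 at p below 1e-09 and 42677 when a call in at least 2 single libraries was required, but 140575 with all deposited reads and 128175 with a genome-wide background alone.

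The X and Y chromosomes separated the libraries as labelled. X held 4.25% ± 0.078 (SD, n = 4) of the retained reads in females and 2.503% ± 0.085 in males (exact permutation p = 0.0286, two-sided, the smallest possible; 0.1 after Benjamini-Hochberg adjustment over 7 library measures). Y held 0.00148% ± 0.00062 in females and 0.0184% ± 0.0083 in males, with the same exact p of 0.0286 and the same adjusted value. Male Y shares were 0.0111% and 0.0115% in set G73 and 0.0254% and 0.0257% in set G76.

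No difference in the number of HNF6 sites was detected between female and male livers. At an equal depth of 2702885 reads, single female libraries gave 31410 ± 3614 sites (SD, n = 4) and male libraries 34797 ± 7984. The exact permutation p was 0.543, two-sided, and 0.8 after adjustment over the 7 measures. Site numbers also went with library set. In set G73 females gave 33449 and 34996 sites and males 34131 and 46220. In set G76 females gave 30379 and 26815 sites and males 28311 and 30525. The SDs and the permutation test, which exchanged libraries between sets, therefore took in the set difference as well as the spread between mice. A sex difference within sets was not tested. Male replicate 2 alone gave 46220 sites, and without it the male minus female difference in means was -420.8 sites. Pools of each sex at equal depth held 69193 female and 73486 male sites. Of the female sites 70.5% overlapped a male site, and of the male sites 66.4% overlapped a female site. Taken over both pools 68.4% of sites were shared, against 70.7% to 71.1% in 8 pairs of pools that mixed the sexes within library sets. The sharing between the sexes was below all 8 mixed pairs.

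HNF6 binding was called different by sex at 7.41% of the tested autosomal sites, most of them higher in males. Sites not called are not shown to be alike, since 30% of 2-fold changes were recovered in simulated data. An unadjusted limma p below 0.05 was found at 6950 of the 33330 sites. Among 33330 autosomal sites, 1942 were higher in males and 527 higher in females, so that 78.7% of the called sites were male-higher. The called differences were also larger at male-higher sites, with a median of 2.70-fold over the male-higher sites and 1.81-fold over the female-higher ones. Both medians cover called sites alone. The male-higher sites were weaker, and weaker sites need a larger difference to be called. At least a 2-fold difference was seen at 1501 male-higher and 195 female-higher sites, and at least a 4-fold difference at 464 and 20. The 4 male values lay entirely above the 4 female values at 1427 of the 1942 sites, and the 4 female values above the male ones at 295 of the 527. These sites had been chosen for a difference. Over all 33330 tested sites the values separated in this way at 2150 (males above) and 1134 (females above), together 9.85%, where chance gives 2.86%. Among the called sites, differences were mostly in level and less in the presence of a site. Of the male-higher sites, 1748 (90.0%) also had a site in the female pool, and 516 of the female-higher sites (97.9%) had one in the male pool. Only sites with at least 10 reads in at least 4 libraries were tested, which favours sites found in both sexes. Over all sites of the pools, 70.5% of female and 66.4% of male sites overlapped one of the other sex. Calls are made more easily at stronger sites, and the called sites had median levels of 31.8 (male-higher) and 46.7 (female-higher) RPM, reads at a site per 1000000 scaled reads in the tested sites, against 18.1 at the other tested sites. The counts depended on single libraries and settings: male-higher sites numbered 989 without female 3, 982 with scaling on background bins and 1175 without the library-set term. Female-higher sites numbered 292 without female 1, 237 without female 2, 296 without female 3, 278 without male 1, 304 without male 2, 199 without male 3, 117 without the library-set term, 238 at equal depth and 228 with limma-trend.

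**Figure D1:**
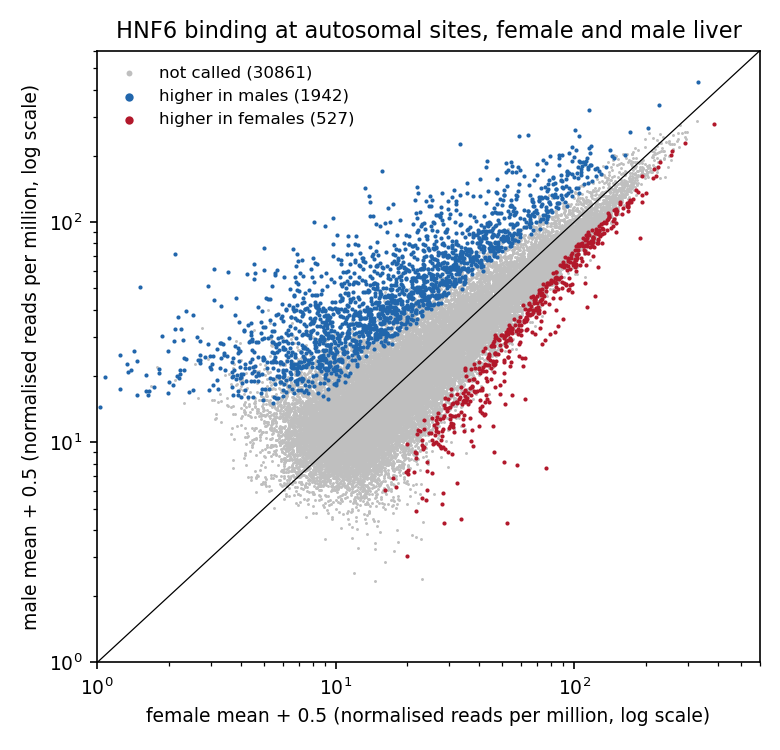
Each point is an autosomal HNF6 site, with the mean of the 4 female libraries on the horizontal and of the 4 male libraries on the vertical axis (RPM plus 0.5, log scales). The 1942 sites higher in males spread farther from the diagonal of equal levels than the 527 sites higher in females.

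The male-higher sites with the smallest adjusted p differed by 2.46-fold to 11.4-fold. A site on chromosome 19 (mm9 46173851 to 46175300) had 15.2 ± 4.9 RPM in females and 170.3 ± 32.2 in males (SD, n = 4), a log2 difference of 3.51 ± 0.28 (SE; limma adjusted p = 1.61e-06). A site on chromosome 18 (12713651 to 12714450) had 13.5 ± 8.7 in females and 122.5 ± 36.3 in males (log2 3.49 ± 0.31, limma adjusted p = 2.80e-06). A site on chromosome 17 (49553401 to 49553950) was 7.04-fold higher in males, one on chromosome 9 (61890601 to 61891250) 6.46-fold, one on chromosome 11 (111858251 to 111858850) 6.42-fold, and one on chromosome 2 (78496251 to 78496850) 5.35-fold. The site on chromosome 13 (75035201 to 75035700) was 5.12-fold higher in males, and that on chromosome 11 (97304601 to 97305200) 4.14-fold. Smaller differences were found at strongly bound sites. The site on chromosome 1 (39189651 to 39190350) had 115.2 ± 36.0 in females and 322.6 ± 105.2 in males (log2 1.55 ± 0.13). The site on chromosome 11 (21021451 to 21022050) had 100.1 ± 15.6 and 260.2 ± 46.4 (log2 1.30 ± 0.11). Sites on chromosome 19 (49434051 to 49435350) and chromosome 12 (31026601 to 31027550) were 3.16-fold and 2.86-fold higher in males. All 12 had a limma adjusted p of 2.83e-06 or below.

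The female-higher sites with the smallest adjusted p differed by 2.27-fold to 4.12-fold. The site on chromosome 10 (33577151 to 33577700) had 61.7 ± 16.5 RPM in females and 15.1 ± 3.2 in males (SD, n = 4), a log2 male minus female difference of -2.04 ± 0.27 (SE; limma adjusted p = 0.000103). Of the 12 sites, 3 lay on chromosome 5: one (146188501 to 146189250) had 188.0 ± 31.7 in females and 84.5 ± 22.5 in males, and those at 146225101 to 146226000 and 146548351 to 146549600 were 3.49-fold and 2.45-fold higher in females. A site on chromosome 7 (14399251 to 14399800) had the smallest adjusted p, 3.63e-05 with limma, with 121.2 ± 25.9 in females and 45.7 ± 13.8 in males. Females were higher by 3.11-fold on chromosome 12 (78391051 to 78391550), 2.87-fold on chromosome 9 (108913701 to 108914250) and 2.73-fold on chromosome 2 (49998951 to 49999550). The difference was 2.67-fold on chromosome 9 (113742601 to 113743100), 2.61-fold on chromosome 8 (92039851 to 92041050), 2.54-fold on chromosome 3 (98692101 to 98693100) and 2.34-fold on chromosome 10 (99018451 to 99019150). In set G73 alone the site on chromosome 12, that on chromosome 8 and the last one on chromosome 10 lost their call (limma adjusted p = 0.0777, 0.0639 and 0.145).

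**Figure D2:**
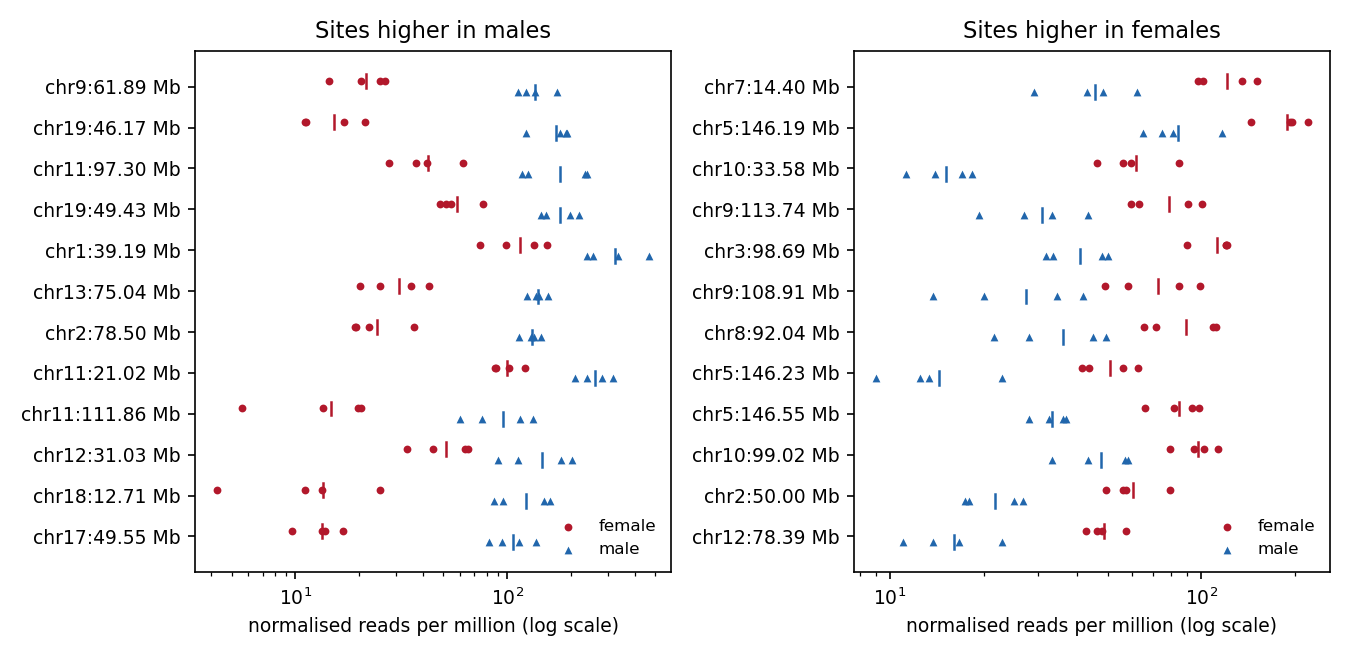
RPM (log scale) in each library at the 12 sites per direction with the smallest adjusted p, with circles for females, triangles for males and vertical ticks for the means of 4 mice. By the rule that chose them, the female and male values do not overlap at any of the 24 sites.

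Of the 5 most strongly bound sites 3 passed the test, with differences in both directions. The site with the highest mean level, on chromosome 17 (30800051 to 30800800), had 329.0 ± 73.1 RPM in females and 433.5 ± 52.9 in males (SD, n = 4; log2 0.43 ± 0.13 SE, limma adjusted p = 0.0496). On chromosome 8 (95757401 to 95758450) females had 386.3 ± 31.1 and males 277.0 ± 40.1 (log2 -0.40 ± 0.09, limma adjusted p = 0.00652). On chromosome 2 (63699451 to 63700400) males were higher, 340.3 ± 29.5 against 226.8 ± 37.6 (log2 0.63 ± 0.10, limma adjusted p = 0.000446). The sites on chromosome 5 (64179301 to 64181250) and chromosome 16 (26705901 to 26707100) did not pass the test, with log2 differences of -0.18 ± 0.07 (limma adjusted p = 0.106) and 0.02 ± 0.09 (limma adjusted p = 0.938). The call on chromosome 17 was lost in 12 of 21 alternatives, with a limma adjusted p of up to 0.273; it was 0.0583 without female 1, 0.157 without female 2, 0.234 without female 3, 0.101 without male 2 and 0.109 without male 4. Its log2 difference ranged from 0.21 without female 3 to 0.63 without female 4, where the limma adjusted p was 0.000887. The calls on chromosomes 8 and 2 were each lost in 1 alternative, with adjusted p of 0.280 in set G76 alone and 0.0763 with scaling on background bins.

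The sex difference was recovered separately in each library set, with 2 mice per sex in each. Set G73 alone gave 631 male-higher and 154 female-higher sites, and set G76 alone gave 825 and 54. Of the male-higher sites called in G73, 97.3% were also higher in males in G76, and 84.9% had an unadjusted limma p below 0.05 there. Of those called in G76, 97.0% had the same direction in G73. The male-higher lists shared 341 sites, where independent lists of these sizes would share 15.6. Of the female-higher sites called in G73, 80.5% had the same direction in G76, and 31.2% an unadjusted limma p below 0.05. The female-higher lists shared 11 sites against 0.2495 for independent lists. Sex separated the libraries along the first principal component of the tested sites (28.2% of the variance), and the second (25.7%) set the G76 libraries apart from those of G73.

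**Figure D3:**
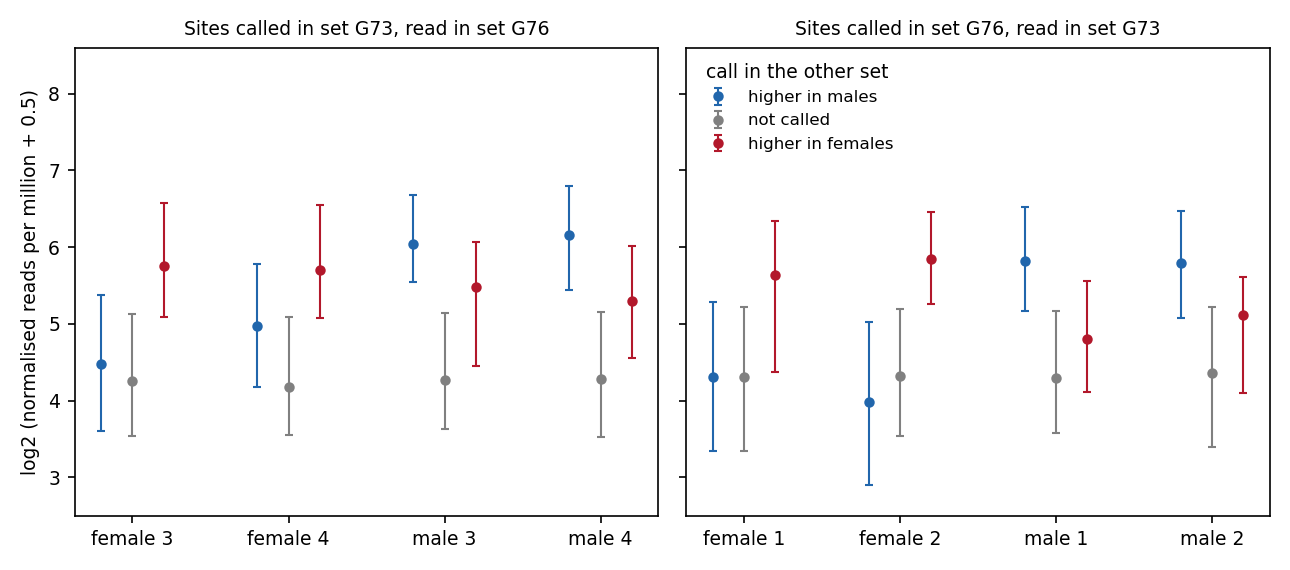
Median and interquartile range of log2 (RPM + 0.5) over sites called in 1 library set, read in the 4 libraries of the other set. Male-higher sites were at a median log2 of 6.05 and 6.16 in males 3 and 4 and of 4.48 and 4.97 in females 3 and 4, and at 5.82 and 5.79 in males 1 and 2 and 4.31 and 3.99 in females 1 and 2.

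On X, the reads behind the sites and the reads between them did not follow the sexes alike. X background reads, relative to autosomal background, were lower in males by a log2 difference of -1.02, a male level 0.493 times the female one (exact permutation p = 0.0286, two-sided, n = 4 per sex). Reads in X sites, relative to autosomal sites, differed by -0.31, a male level 0.805 times the female one (exact permutation p = 0.0286, n = 4 per sex). The gap between the measures was 0.71 on the log2 scale, with the 4 male values above the 4 female values (exact permutation p = 0.0286, n = 4 per sex). These tests exchanged libraries between the library sets, and exchange within sets alone allows no share below 5.56%. Over 1286 tested X sites the median log2 male minus female was -0.33. Over all 3193 X sites, tested or not, the median log2 of male over female means was lowest at weak sites, -0.73 below 5 RPM, and was -0.21 at sites between 10 and 20 and -0.25 at 40 or more. Called sites on X numbered 31 higher in males and 21 higher in females. These calls were made against a log2 of 0 with the autosomal scaling, so they do not allow for X copy number. The X site with the smallest adjusted p among those higher in males, chosen after its values were seen, was at 54263401 to 54263950, with 18.3 ± 7.9 in females and 78.7 ± 9.3 in males. Its female-higher counterpart, chosen in the same way, was at 100694551 to 100695100, with 186.9 ± 34.8 and 94.1 ± 28.5 (limma adjusted p = 8.43e-05 over X sites for each). The log2 male minus female at this female-higher site was -1.03, close to the X background difference of -1.02. It therefore shows no sex difference beyond that of X background. With sites called in at least 2 single libraries the difference in X-site reads was -0.19.

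**Figure D4:**
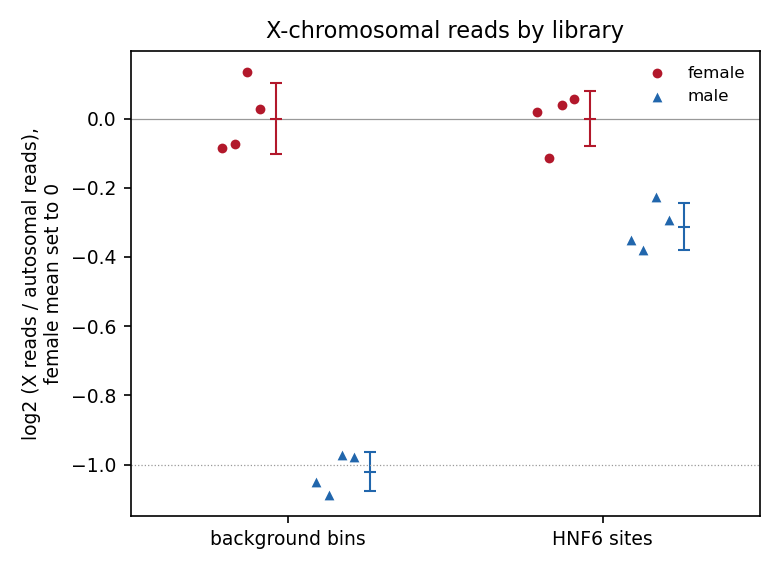
Log2 of X over autosomal reads in each library, in background bins and in HNF6 sites, with the female mean set to 0; bars give the mean and SD of 4 mice, and the dotted line marks a log2 of -1. Male libraries lie 1.02 below the female mean in background, a difference of -1.02, and by a difference of -0.31 in sites.

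No autosome passed a test for an excess or deficit of called sites. In 38 Fisher's exact tests, 1 per autosome and direction, the smallest Benjamini-Hochberg adjusted p was 0.190. Chromosome 3 had the smallest unadjusted p, 0.00653, with 154 of 2142 tested sites higher in males (7.19%; odds ratio 1.27; adjusted p = 0.190). The highest share of male-higher sites was on chromosome 18, with 92 of 1228 tested sites (7.49%; adjusted p = 0.190), and chromosome 15 had 62 of 1423 (4.36%; adjusted p = 0.190).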

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

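The tests of library scaling, of male reads in female replicate 4 and of scaling or background of that library were chosen after the result was seen; the tests of the surroundings, of chance and of X copy number were written before it.

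More sites were higher in males than in females, 1942 against 527, and over 3 scalings of the libraries the share of called sites higher in males was lowest at 72.8%, with background bins, which argues against scaling as the whole cause. Reads around the male-higher sites had a median log2 male over female of 0.10, against 1.43 at the sites, so background or copy number of the surrounding DNA moved by 7.27% of that difference, or 23.0% against other sites (48.7% and 22.3% at female-higher sites). Of the 35 splits of the 8 libraries into 4 and 4, 1, the split by sex, gave as many sites, 2469 with the library-set term. The highest other count was 241, for the split by library set without a sex term. Like for like, sex gave 1292 sites without a library-set term, and library set gave 1875 with sex as a term. The library sets differed, so free exchange between them does not hold and the 35 splits cannot exclude chance. Exchange within library sets leaves 18 splits, too few for a share below 5% (1 of 18 is 5.56%), with 2469 sites for the split by sex and at most 0 for another, where mixed splits carry the sex difference as spread. A biological difference in HNF6 binding between female and male liver may underlie the pattern, a hypothesis found and tested on the same libraries, and the levels of HNF6 itself were not analysed here.

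X sites were reduced in males by less than X background. If X copy number alone set the level, sites and background would differ alike, but the median log2 male over female of X sites lay 0.69 above that of X background. Lower HNF6 binding to the inactive X of females is a candidate explanation. It was not tested, since reads from the active and the inactive X were not told apart.

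Female replicate 4 lay between the sexes at male-higher sites. At the 631 male-higher sites of set G73, the median log2 of female 4 over female 3 was 0.43, while male 4 over male 3 was 0.04. This sets 1 library against 1 other and does not show which of them moved. At the male-higher sites of set G76, called with female 4 and without female 1, female 1 (median log2 4.31) lay above female 4 (4.23). At those of set G73, called with female 1 and without female 4, the order was reversed (4.78 and 4.97). Female 1 and female 4 can therefore not be ranked from these lists. A mixture with male chromatin would need 20.9% male reads at the 631 sites of set G73 and a Y share 0.00517% above that of female 3. The share in female 4 was 0.00108% (Wilson 95% interval 0.000850% to 0.00138%) and the excess 3.82% of what was needed. For scaling or background of female 4, 10000 lists of other sites were matched on their level in females 1 and 2. The median at the male-higher sites lay 0.35 above the highest of them. This argues against scaling, which moves all sites alike. Background cannot be decided, since the lists were not matched on the reads around the sites. Around the 1942 male-higher sites those reads had a log2 male over female 0.33 above that around other sites. Female 4 also had 29.5% of its reads in sites against 32.9% in female 3. A difference between individual females, such as hormonal state, may remain and was not tested.

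At the female-higher site on chromosome 3 (98692101 to 98693100), female 4 had 89.8 RPM and the other females 119.8, 119.9 and 120.8, a gap of 0.971 of the range; chance marks about 1 in 20 groups in this way, and 1 of 72 groups was marked.

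The sex difference itself differed between the library sets at 4 of 33330 sites (limma interaction, adjusted p below 0.05; 1398 sites had an unadjusted p below 0.05). The log2 interaction, set G76 minus set G73, was 4.21 on chromosome 1 (127440701 to 127441250), 6.55 on chromosome 1 (189032301 to 189032850), -4.74 on chromosome 3 (98945151 to 98945700) and -3.91 on chromosome 16 (6776501 to 6777100). At the chromosome 16 site males 3 and 4 had 9.99 and 5.998 RPM, and the other 6 libraries between 93.4 and 131.8.

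Reads outside the assembled chromosomes entered no comparison; their share of the deposited reads was highest in female replicate 1, at 1.39%.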

How the results depend on the processing

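Keeping repeat stacks and sites without strand offset, and the number of sites called in at least 2 single libraries, were chosen after seeing the data; the other alternatives were set before the data were examined. More sites were higher in males than in females under every alternative run. The total, the male-higher and the female-higher counts (2469, 1942 and 527) became 1349 and 982 (total and male-higher) with scaling on background bins, which moved the median log2 of all sites from -0.04 to -0.20. They became 1292, 1175 and 117 without the library-set term, 785, 631 and 154 in set G73 alone and 879, 825 and 54 in set G76 alone; the set-alone values rest on 4 libraries each. At equal depth the total was 1586 and the female-higher count 238, with limma-trend 1641 and 228, and with a 2-fold minimum 195 were female-higher. Leaving out 1 library gave totals of 1285 to 2415, male-higher counts of 989 to 1886 and female-higher counts of 199 to 584, with fewer samples in each fit. The total was lowest without female 3 (1285) and fell to 1572 without female 2. With repeat stacks kept, 1932 and 475 sites were called. Apart from these, the causes of the shifts were not tested.

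The number of sites was 62232 at p below 1e-09 and 42677 with a call in at least 2 single libraries, 140575 with all deposited reads and 128175 with a genome-wide background. Shared sites made up 68.1% with an overlap of at least 50% and 75.4% at p below 1e-09, below the mixed pools in each case (70.4% to 70.8% and 78.5% to 79.2%). The log2 difference in X-site reads was -0.24 at p below 1e-09 and -0.19 with sites called in at least 2 single libraries. The 12 named male-higher sites kept their call in 261 of 261 checks under an alternative, and the female-higher ones in 261, with 3 lost in set G73 alone. Both groups had been chosen for the smallest adjusted p in the same libraries, which favours keeping the call. At the 5 strongest sites 14 checks lost a call, 12 of them on chromosome 17 (30800051 to 30800800), and 91 did not change the outcome. At this depth and number of mice 30% of simulated 2-fold changes were recovered, with the same spread at every site. The limits set by depth and by spread were not separated. The count-model alternative and those for neighbouring genes and motifs were not run.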

Other observations

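The comparisons in this part were chosen after the data were seen. Female-higher sites lay near each other more often than shuffled calls did. Of the 527 female-higher sites, 72 had another female-higher site 5 to 50 kb away, against a mean of 30.04 and a highest value of 53 in 1000 shuffles of the calls among sites of like level (permutation p = 0.001, the smallest that these shuffles can give). Of the 1942 male-higher sites 353 had a male-higher neighbour, against a shuffled mean of 352.5 (permutation p = 0.5, one-sided). Pairs of opposite direction were rare, 32 against a shuffled mean of 113.0 and a lowest value of 77.

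Stretches with at least 3 called sites of the same direction, each at most 50 kb from the next, numbered 38 for male-higher and 8 for female-higher sites. The shuffles gave a mean of 25.5 and a range of 13 to 39 for male-higher sites (permutation p = 0.004, one-sided), and a mean of 0.763 and a range of 0 to 5 for female-higher sites (permutation p = 0.001, the smallest possible). Unlike the neighbour count of 5 to 50 kb, stretches had no lower distance limit. On chromosome 18 (64766501 to 64769350) 3 male-higher sites lay within 2.85 kb. Whether such close sites made up the male-higher excess was not tested. On chromosome 4 (103054801 to 103068900) all 5 tested sites were higher in males, with a median log2 of 3.30. On chromosome 6 (141941001 to 141960600) all 5 tested sites were male-higher, with a median log2 of 2.10, and on chromosome 2 (53612201 to 53684650) all 4, with 2.68. On chromosome 16 (24240701 to 24350000) 5 of 13 tested sites were male-higher, with a median log2 of 1.09. Female-higher stretches included chromosome 5 (146187851 to 146226000), with 5 of 5 tested sites and a median log2 of -0.98, and chromosome 10 (33507251 to 33625150), with 5 of 7 and -1.08. On chromosome 7 (26984251 to 27012350) all 3 tested sites were female-higher, with a median log2 of -3.36.

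The female libraries of set G73 also differed from each other at male-higher sites. At the 825 male-higher sites of set G76, read in set G73, the median log2 of female 2 over female 1 was -0.18, outside the range of -0.09 to 0.17 of 10000 lists of other sites matched on their level in females 3 and 4. This sets 1 library against 1 other, and female 1 had 25.9% of its reads in sites against 29.8% in female 2. Male 2 over male 1 gave -0.02, within the range of -0.09 to 0.10 of lists matched on the mean level of all libraries.

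Some sites were nearly empty in a single mouse. Among sites not called by sex and with at least 30 reads predicted from the other libraries, 68 of 17598 had at most 3 reads in female 3, 22 of 13164 in female 4, 25 of 14887 in male 3 and 17 of 8871 in male 4, all of set G76. In set G73 they numbered 0 of 3532 in female 1, 3 of 5754 in female 2, 0 of 6620 in male 1 and 1 of 4529 in male 2, so such sites went with library set. Reads around these sites, as log2 against the other libraries, were at -0.60 in female 2, -0.08 in female 3, -0.24 in female 4, -0.99 in male 2, -0.43 in male 3 and -0.53 in male 4. Around the remaining sites of the same kind they were at -0.20, 0.53, 0.29, -0.50, -0.07 and 0.14 in the same libraries. Counts drawn with the median spread between libraries gave 0 such sites on average in each of these libraries; sites with a larger spread of their own would give more.

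Library set also went with the scaled reads at sites: 1875 of the 33330 autosomal sites differed between sets G73 and G76 (limma adjusted p below 0.05). The sets also differed in interval length, 35 bp in G73 and 40 bp in G76. Technical differences and differences in binding were not told apart.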
